A study of Mus musculus with 8 samples.

How the data were processed

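Colon tissue of C57BL/6 mice with DSS colitis was compared between 4 libraries from mice given PAGly at 100 mg/kg and 4 from mice given saline, all over 9 days. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a directional kit. Per the submitters' processing notes, the tools included HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2, with genome build GRCm38. Which step each tool served, the annotation release and whether counting used strand are not given in the sources used here, so genes that overlap on opposite strands carry that uncertainty. Each deposited table gave, per the file headers, a read count and a TPM (transcript abundance) value for each RefSeq RNA. The deposited read counts were not all whole numbers, as 47.8% of all values, zeros included, were exactly whole. The read counts, as deposited by the authors, were therefore taken to be estimated counts (expected counts) of the kind RSEM gives, not normalized between libraries. The deposited TPM values, normalized by the authors for transcript length and depth, were used only in alternatives.

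The tables held 57305 transcripts (27585 curated and 29720 predicted RefSeq models) of 18000 gene symbols. Of the transcript IDs, 96.9% matched the RefSeq gene table for the same assembly, from which coordinates were taken. The 25 transcripts without a symbol held 0.0065% to 0.0098% of the counts of a library and were left out. Expected counts were summed over the transcripts of a symbol and rounded to whole numbers. The totals ran from 14604578 to 16986683 per library. The 20 most abundant genes took 10.2% to 11.6% of them, and the most abundant, Lypd8, took 1.19% to 2.03%.

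Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 14077. Library sizes were scaled with TMM factors, and PAGly was compared with saline by the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median prior degrees of freedom of the fit were 3.32 and the common biological coefficient of variation was 0.302. Standard errors were computed as the log2 fold change divided by the square root of the F statistic. The labels give no batch or pairing, and replicate numbers only name libraries, so no block was fitted.

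Before the data were examined, 46 gene lists of pathways and cell types, the platelet list among them, the fixed panel of 25 genes, the rule for naming genes, the tests and most alternatives were written down. The 43 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Of the other 3 lists, pancreas had 2 tested members, skeletal muscle 4 and mitochondrial transcripts 0. Each list's mean log2 CPM was compared by an exact two-sided permutation test over 70 assignments. The edgeR p-values were also adjusted over the members of each list alone, with no correction for the number of lists. That adjustment had been written down beforehand for the platelet list only. Genes are named by 3 rules: up to 12 genes per direction past the threshold with groups that do not overlap, up to 4 members of each list with the smallest p, and the fixed panel. Results of 4 of these genes are not reported here, and they stayed in every test. The first rule fills up to 5 genes by smallest p where fewer pass, as happened in both directions. Hox genes, Mfap4 and Mptx1 were chosen after their values were seen, as was the Hox index. The index is the mean log2 CPM of Hoxb13 and Hoxd10 to Hoxd13 minus that of Hoxb3 to Hoxb8, Hoxd3, Hoxd4 and Hoxd8.

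The alternatives were RLE factors, library totals alone, no filter, a filter of at least 1 CPM in 4 libraries, removal of the 20 most abundant genes, and 1 surrogate variable from sva 3.50.0. Others were DESeq2 1.42.0 with its own size factors, limma-voom with quality weights, limma on log2(TPM + 1) and on log2(TPM + 0.1), other thresholds, and each library left out in turn. After the data were seen, the Hox index as a covariate, the joint removal of PAGly replicate 1 and saline replicate 1, each library left out in DESeq2, and edgeR without its robust option were added. The comparison was also repeated for the 35 splits of the libraries into 4 and 4. The procedure was tested on counts simulated for the comparison of 4 PAGly with 4 saline libraries over 14077 genes, with 200 genes changed. edgeR recovered 38 of 100 genes changed 2-fold and 83 of 100 changed 4-fold and called 8 unchanged genes, while DESeq2 recovered 63 and 90 and called 42 unchanged genes. Camera called 4 of 200 lists of unchanged genes at an unadjusted p under 0.05. The simulated genes varied independently of each other, so this could not test the preset correlation on lists whose members vary together. In the data the estimated correlation was, for example, 0.36 for the macrophage list and 0.845 for interferon-stimulated genes.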

Results

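Messenger RNA of colon tissue was sequenced from C57BL/6 mice with colitis induced by dextran sodium sulfate (DSS), a polysaccharide that injures the colonic epithelium. The mice received intraperitoneal injections of phenylacetylglycine (PAGly) at 100 mg/kg or of saline over 9 days. PAGly is formed from phenylacetic acid, a product of bacterial phenylalanine breakdown, and in mice it takes the place of human phenylacetylglutamine. There were 4 PAGly and 4 saline libraries, and no untreated animals without DSS were among the samples used here. The deposited expected counts summed to between 14604578 and 16986683 per PAGly library and between 14853156 and 16421532 per saline library. Levels are given as CPM, which are counts scaled to library totals corrected by TMM factors. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom was at least 28.5 for every pair. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these libraries.

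The first comparison asked which genes of the inflamed colon differed between PAGly and saline. Among the genes lower with PAGly, the smallest p-values began with Ankrd37, a target of hypoxia-inducible factor, with 9.47 ± 1.14 CPM against 35.5 ± 8.62 with saline (SD, n = 4 each). Next came Sema7a, a membrane-anchored semaphorin, with 3.10 ± 0.32 against 11.8 ± 3.12 CPM. Dgat2, an enzyme of triglyceride synthesis, had 40.5 ± 5.67 against 105.2 ± 20.7 CPM. Creb3l3, a transcription factor of lipid metabolism, had 4.10 ± 1.84 against 24.9 ± 7.60 CPM. Lama3, a laminin chain of epithelial basement membranes, had 24.7 ± 2.94 against 92.7 ± 34.6 CPM. On the other side, Sema5a had 79.0 ± 10.7 CPM with PAGly and 39.8 ± 4.76 with saline. The matrix proteoglycan gene Bgn had 150.7 ± 42.3 and 59.0 ± 5.51, and the heparin-binding growth factor gene Ptn had 34.6 ± 9.60 and 10.7 ± 2.88. Apoe, which encodes a lipoprotein component made by macrophages among other cells, had 367 ± 32.9 and 216 ± 10.9, and the angiotensin-converting enzyme gene Ace had 51.0 ± 5.32 and 23.4 ± 5.54. For each of these 10 genes every PAGly library lay on one side of every saline library.

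None of these genes passed the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 14077 genes tested. The log2 fold change was -1.91 (SE 0.21) for Ankrd37, -1.93 (SE 0.23) for Sema7a and -1.38 (SE 0.17) for Dgat2, each with an edgeR adjusted p of 0.0668. It was -2.60 (SE 0.36) for Creb3l3 and -1.91 (SE 0.27) for Lama3, each with 0.119. It was 0.99 (SE 0.14) for Sema5a with an edgeR adjusted p of 0.119. It was 1.35 (SE 0.20) for Bgn, 1.69 (SE 0.26) for Ptn, 0.77 (SE 0.12) for Apoe and 1.13 (SE 0.18) for Ace with 0.127 each. On build GRCm38, Ankrd37 lies on chromosome 8 from 45996908 to 46000414, Sema7a on chromosome 9 from 57939596 to 57962865, and Dgat2 on chromosome 7 from 99153663 to 99182713. Sema5a lies on chromosome 15 from 32244813 to 32696341 and Apoe on chromosome 7 from 19696244 to 19701310.

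In total, edgeR called 0 genes higher and 0 lower with PAGly at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1772 genes, 812 higher and 960 lower, where chance alone would give about 704 on average. This excess does not set the treatment apart. Of the 35 splits of the libraries into 4 and 4, the real one included, 5 gave at least 1772 such genes. The groups did not overlap for 1042 genes, or 7.40% of those tested, against 2.86% by chance as an average over all assignments. Because genes vary together, a single split can differ from that average, and this count was not made for the other splits. DESeq2, which tested 15838 genes, called 188 genes higher and 186 lower. All 10 genes above were among them, with DESeq2 adjusted p from 3.12e-12 for Ankrd37 to 2.52e-05 for Ace. In the simulated counts, DESeq2 called 42 unchanged genes where edgeR called 8. The DESeq2 counts from the data changed with the library left out. They were 80 higher and 77 lower without PAGly replicate 1, and 36 and 39 without PAGly replicate 2. They were 438 and 681 without saline replicate 1, 166 and 92 without saline replicate 2, and 140 and 90 without saline replicate 4. The total of both directions moved least without PAGly replicate 3 (200 and 218), PAGly replicate 4 (174 and 224) or saline replicate 3 (257 and 131). edgeR called 1 gene higher and 4 lower without saline replicate 1, and 0 in both directions when any other single library was left out.

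**Figure D1:**
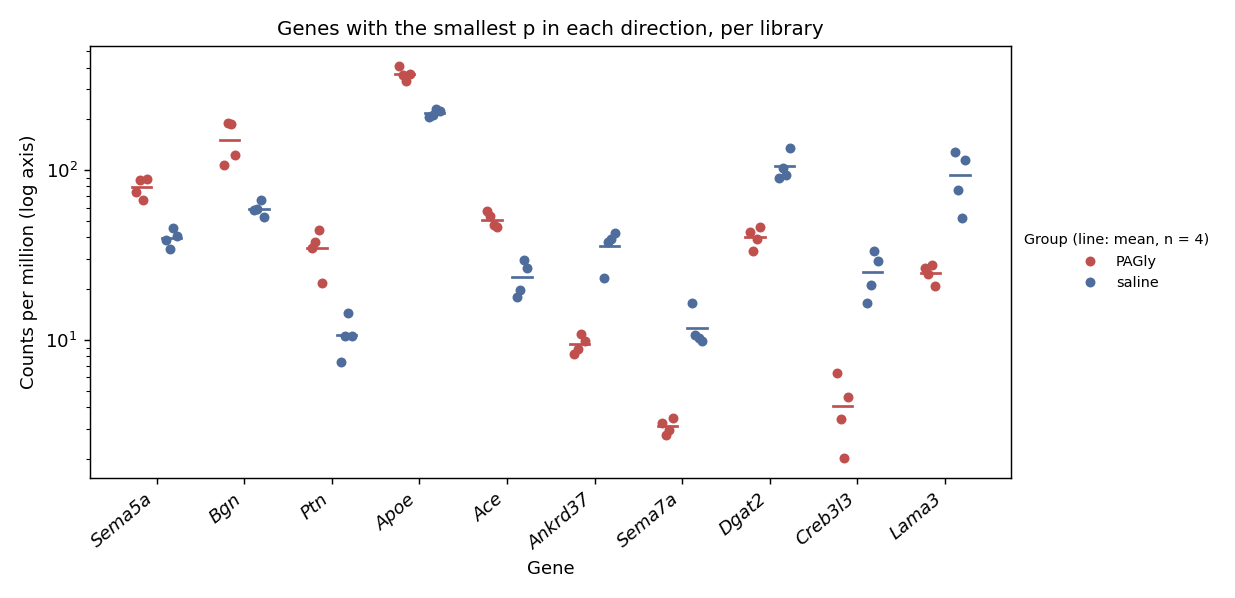
CPM on a log axis for the 10 genes with the smallest p-values, 5 in each direction, with 1 point per library, a line at each group's mean (n = 4), PAGly in red and saline in blue. In each gene the points of the 2 groups do not overlap, for example 8.27 to 10.9 CPM against 23.0 to 42.5 CPM for Ankrd37.

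The second comparison asked which cell types and pathways differed, using gene lists fixed beforehand. Macrophage genes rose as a group with PAGly: 20 of the 21 tested members of the monocyte and macrophage list had a positive log2 fold change, with a median of 0.65 (camera adjusted p = 1.55e-07, and adjusted p = 0.646 with an estimated correlation). The complement component genes C1qa, C1qb and C1qc, which macrophages of the gut wall express, had 49.7 ± 7.47, 53.7 ± 12.9 and 37.5 ± 6.41 CPM with PAGly against 31.4 ± 3.65, 32.1 ± 4.34 and 21.6 ± 2.65 with saline (SD, n = 4). Gpnmb, a lysosomal glycoprotein gene of macrophages, had 7.56 ± 2.07 against 2.65 ± 0.83 CPM. Of the 21 macrophage genes, 8 passed when adjusted over the list alone and 0 over all genes in edgeR. The complement list, which shares the C1q genes, also rose, with 15 of 17 members positive and a median of 0.40 (camera adjusted p = 0.000189, and 0.646 as the adjusted p with an estimated correlation). In it, Cfb, which encodes factor B of the alternative pathway, had 235 ± 49.6 against 112 ± 34.5 CPM. When adjusted over the list alone, 4 members passed: Cfb and the shared C1qa, C1qb and C1qc, already counted among the macrophage genes.

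Fibroblast and extracellular matrix genes rose, with 20 of 24 members positive and a median of 0.77 (camera adjusted p = 4.44e-05, and adjusted p = 0.646 with an estimated correlation). The list's mean log2 CPM was 5.28 and 5.90 in PAGly replicates 2 and 3, and 4.71 and 4.68 in PAGly replicates 1 and 4. Saline replicate 1, at 5.17, lay above the latter (exact permutation p = 0.171). Collagen genes led in PAGly replicates 2 and 3: Col1a1 had 318 and 424 CPM there. It had 105 and 90.8 CPM in PAGly replicates 1 and 4, and 56.5 to 101.6 CPM with saline. Col1a2, Sparc and Postn had log2 fold changes of 1.30 (SE 0.39), 1.00 (SE 0.26) and 0.84 (SE 0.24), and 0 members passed when adjusted over the list alone. T and natural killer cell genes fell, with 12 of 13 members negative and a median of -0.83 (camera adjusted p = 0.000130, and adjusted p = 0.646 with an estimated correlation). The cytotoxic granule genes Gzma and Gzmb had 1.11 ± 1.02 and 0.86 ± 0.68 CPM with PAGly against 4.45 ± 1.74 and 3.74 ± 1.75 with saline, and Cd8a had 1.25 ± 0.60 against 3.62 ± 1.70 (SD, n = 4). These 3 genes and Zap70, a kinase of T-cell receptor signalling, were the 4 members that passed when adjusted over the list alone.

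The list of mast cell and eosinophil genes rose, with 5 of 6 members positive and a median of 0.51 (camera adjusted p = 0.0311, and adjusted p = 0.646 with an estimated correlation). Its mean log2 CPM was 1.84 ± 0.17 with PAGly and 1.17 ± 0.072 with saline, and the groups did not overlap (exact permutation p = 0.0286, the smallest 4 against 4 can give). Mcpt1, a mast cell protease gene, had 3.52 ± 1.27 against 1.83 ± 0.53 CPM, and Cma1 ranged from 5.09 to 10.9 CPM with PAGly and from 0.13 to 7.54 with saline. The 1 negative member was Siglecf, an eosinophil gene, with a log2 fold change of -0.94 (SE 0.64) that came from 1 library, as it was 0.076 without saline replicate 2, which had 5.56 CPM. Endothelial genes rose by a median of 0.26, with 13 of 19 members positive (camera adjusted p = 0.0160, and adjusted p = 0.646 with an estimated correlation). Plvap, a gene of fenestrated vessels, had 37.7 ± 6.49 against 25.8 ± 3.84 CPM. Interferon-stimulated genes rose by a median of 0.29 with 18 of 23 members positive (camera adjusted p = 0.000955, and adjusted p = 0.869 with an estimated correlation). Saline replicate 4 had the highest mean level of this list among the 8 libraries, at 6.72 log2 CPM. Its Bst2 and Oas1a stood at 77.1 and 239 CPM, against 22.5 to 26.1 and 67.7 to 120.7 CPM in the other saline libraries and 63.6 to 118 and 163 to 301.5 CPM with PAGly.

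Genes of hypoxia and glycolysis fell with PAGly, with 20 of 23 members negative and a median of -0.29 (camera adjusted p = 0.000133, and adjusted p = 0.646 with an estimated correlation). Besides Ankrd37, the lactate transporter gene Slc16a3 had 19.5 ± 2.93 CPM with PAGly against 59.0 ± 23.5 with saline, the glucose transporter gene Slc2a1 had 157.5 ± 19.2 against 244 ± 32.2, and the phosphofructokinase gene Pfkl had 208 ± 18.5 against 286 ± 27.7 (SD, n = 4). These 4 members passed when adjusted over the list alone, and their groups did not overlap. Erythrocyte genes fell, with 5 of 6 members negative and a median of -1.05 (camera adjusted p = 0.00183, and adjusted p = 0.646 with an estimated correlation): the hemoglobin genes Hbb-bs and Hba-a1 had 17.3 ± 8.07 and 6.01 ± 4.08 CPM against 37.9 ± 12.7 and 14.9 ± 5.10. Their values are uncertain, because near-identical globin copies share reads. The transferrin receptor gene Tfrc, also in this list, had 135 ± 21.7 against 202.5 ± 14.9 CPM. It stood far above the hemoglobin genes, so its fall need not reflect erythrocytes.

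Fatty acid oxidation and ketogenesis genes fell by a median of -0.32, with 19 of 22 members negative (camera adjusted p = 0.00159, and adjusted p = 0.869 with an estimated correlation). Small intestine genes fell by a median of -1.10, with 8 of 11 negative (camera adjusted p = 0.00871, and adjusted p = 0.646 with an estimated correlation). The nuclear receptor gene Pparg had 56.3 ± 15.2 against 103.9 ± 26.5 CPM. The intestinal alkaline phosphatase gene Alpi had 10.5 ± 9.21 against 107 ± 74.7 CPM, and the fatty acid binding protein gene Fabp2 79.2 ± 45.3 against 361 ± 261. The bile acid transporter gene Slc10a2 had 10.6 ± 10.0 against 66.9 ± 29.3, whereas the bile acid binding protein gene Fabp6 had 21.4 ± 8.23 against 7.06 ± 3.84. Both lists moved with the ratio of posterior to anterior Hox genes described below, and with that index in the model their camera adjusted p was 0.544 and 0.156.

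Squamous epithelium genes rose with all 8 members positive and a median of 2.35 (camera adjusted p = 0.000568, and adjusted p = 0.646 with an estimated correlation). PAGly replicate 1 had the highest mean level of the list, and without it the difference in mean log2 CPM was 1.73 instead of 2.81 and the camera adjusted p 0.00422. The basal keratin gene Krt5 had 169.6, 16.7, 15.3 and 0.80 CPM in PAGly replicates 1 to 4 and 0.28 to 1.83 with saline. Lgals7 had 234.5, 45.8, 2.15 and 0.73 CPM in PAGly replicates 1 to 4 and at most 0.53 with saline. Intestinal stem cell genes rose by a median of 0.49 with 12 of 14 positive (camera adjusted p = 0.00251, and adjusted p = 0.823 with an estimated correlation). Smoc2 stood at 43.1 ± 9.11 against 16.7 ± 9.13 CPM, and Lrig1 at 103.1 ± 17.8 against 66.0 ± 23.0. Cytosolic ribosomal protein genes rose by a median of 0.21 with 24 of 25 positive (camera adjusted p = 0.00102, and adjusted p = 0.869 with an estimated correlation). Rps6 had 90.8 ± 15.1 against 57.0 ± 17.4 CPM. Lipid and sterol synthesis genes rose by a median of 0.14 with 16 of 23 positive (camera adjusted p = 0.0145, and adjusted p = 0.869 with an estimated correlation). In that list the fatty acid synthesis genes Acaca and Acly had log2 fold changes of 0.42 (SE 0.12) and 0.75 (SE 0.26), while the elongase gene Elovl6 had -0.99 (SE 0.30).

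In all, camera with its preset correlation called 15 of the 43 lists tested, 10 higher and 5 lower. By contrast, 0 were called with an estimated correlation and 0 by fry, whose lowest adjusted p was 0.222. An exact two-sided permutation test of each list's mean log2 CPM gave 3 lists an unadjusted p of 0.0286 (monocytes and macrophages, mast cells and eosinophils, tight junctions and adhesion), with a lowest adjusted p of 0.410. The calls of 6 lists ended when 1 library was left out. The adjusted p was 0.0742 for stem cells without PAGly replicate 1 and 0.217 without saline replicate 4, and 0.0695 for ribosomal proteins without saline replicate 2. It was 0.0625, 0.0871 and 0.145 for endothelium without PAGly replicate 1, PAGly replicate 3 or saline replicate 3, and 0.0830 and 0.197 for interferon-stimulated genes without saline replicate 1 or 3. For mast cells and eosinophils it was 0.116, 0.146 and 0.0702 without PAGly replicate 4, saline replicate 1 or saline replicate 3, and for lipid and sterol synthesis 0.0513, 0.0580, 0.235 and 0.140 without PAGly replicate 3, PAGly replicate 4, saline replicate 2 or saline replicate 3. With the Hox index described below in the model, a setting chosen after the data were seen, 6 of the 15 lists were no longer called. Besides fatty acid oxidation and small intestine genes, these were stem cells (adjusted p = 0.160), endothelium (0.0519), lipid and sterol synthesis (0.394) and ribosomal proteins (0.444). Their differences in mean log2 CPM went from 0.54 (SE 0.35) to 0.25 (SE 0.34), from 0.26 (SE 0.13) to 0.25 (SE 0.16), from 0.23 (SE 0.17) to 0.077 (SE 0.17) and from 0.24 (SE 0.20) to 0.057 (SE 0.18). For endothelium the difference barely moved and its SE grew, while for the other 3 the difference itself shrank. Of the 9 lists still called, some shrank as well: T and natural killer cells from -0.88 (SE 0.29) to -0.56 (SE 0.20), fibroblasts and matrix from 0.54 (SE 0.35) to 0.27 (SE 0.35), complement from 0.47 (SE 0.25) to 0.28 (SE 0.25), macrophages from 0.64 (SE 0.23) to 0.40 (SE 0.19) and squamous epithelium from 2.81 (SE 1.37) to 1.64 (SE 1.33). The other 28 lists had adjusted p from 0.0506 to 0.969.

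**Figure D2:**
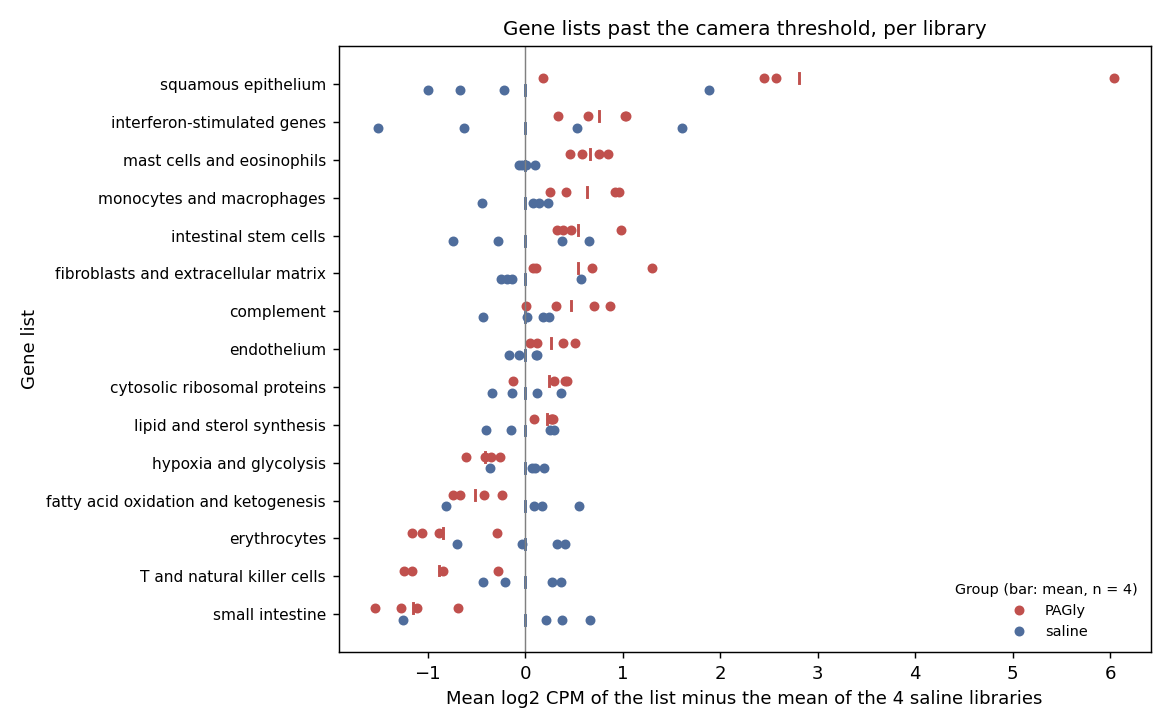
Mean log2 CPM of each of the 15 gene lists called by camera, minus the mean of the 4 saline libraries, with 1 point per library, a bar at each group's mean (n = 4), PAGly in red and saline in blue. The groups separate without overlap for mast cells and eosinophils and for monocytes and macrophages. For macrophages they nearly touch, with 2.71 log2 CPM in PAGly replicate 4 and 2.69 in saline replicate 1 before the subtraction. PAGly replicate 1 stands far to the right for squamous epithelium.

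The third comparison concerned platelets, since the series title names platelet activation. Transcripts of platelets and megakaryocytes were scarce in the colon and showed no difference past the threshold as a group: 6 of the 16 tested members had a positive and 10 a negative log2 fold change, with a median of -0.16 (camera adjusted p = 0.457, and adjusted p = 0.869 with an estimated correlation). The list's mean log2 CPM was 2.12 ± 0.24 with PAGly and 2.15 ± 0.16 with saline (SD, n = 4; exact permutation p = 0.914). Itga2, the integrin alpha-2 gene, which epithelial cells also express, was the only member that passed when adjusted over the list alone, with 20.7 ± 7.46 CPM against 42.6 ± 7.97. It had a log2 fold change of -1.05 (SE 0.25) and an adjusted p of 0.0343 there and of 0.215 over all genes in edgeR. Itga2b, the platelet integrin alpha-IIb gene, had 1.36 ± 0.14 CPM against 2.10 ± 0.21, with at most 1.52 in the PAGly and at least 1.81 in the saline libraries (log2 fold change -0.63, SE 0.25, edgeR adjusted p = 0.339). Gp1bb had 15.5 ± 7.85 against 36.8 ± 12.5 CPM (edgeR adjusted p = 0.255), while its partner Gp1ba had 1.33 ± 0.54 against 1.48 ± 0.50 and Itgb3 7.28 ± 0.78 against 7.50 ± 1.51.

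The platelet chemokine gene Pf4 had 5.16 ± 1.00 CPM with PAGly and 3.39 ± 1.63 with saline, and Ppbp had 23.8, 0.06, 6.57 and 0.53 CPM in PAGly replicates 1 to 4 and 0.066 to 2.18 with saline. The platelet receptor genes Gp6, Gp9 and P2ry12 and the P-selectin gene Selp lay below the count filter. They had at most 11, 6, 19 and 21 counts in any library, so they were not tested in the main fit. Among coagulation genes, Vwf, Thbs1 and F3 had log2 fold changes of 0.26 (SE 0.24), 0.15 (SE 0.33) and -0.042 (SE 0.42), with edgeR adjusted p from 0.707 to 0.978. Proc, the protein C gene, had 1.45 ± 0.61 against 4.69 ± 2.18 CPM and Tfpi, an inhibitor of tissue factor, 7.60 ± 2.02 against 5.08 ± 0.96. In edgeR, 0 of the 20 coagulation and fibrinolysis genes passed when adjusted over the list alone.

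**Figure D3:**
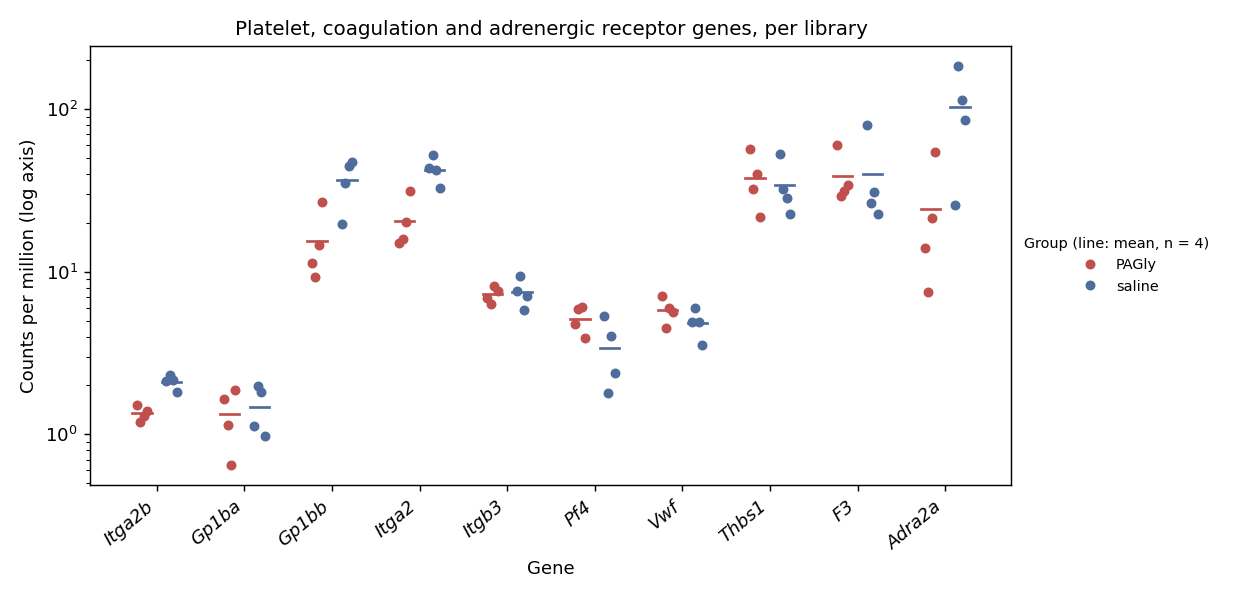
CPM on a log axis for 10 platelet, coagulation and adrenergic receptor genes, with 1 point per library, a line at each group's mean (n = 4), PAGly in red and saline in blue. The groups lie apart in Itga2b and Itga2 and overlap in the other genes shown.

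Adrenergic receptors were examined as reported receptors of phenylacetylglutamine. Adra2a had 24.4 ± 21.0 CPM with PAGly and 102.7 ± 66.0 with saline, a log2 fold change of -2.07 (SE 0.69, edgeR adjusted p = 0.282), and it stood at 54.7 CPM in PAGly replicate 4 and 25.8 in saline replicate 1. With the Hox index in the model its log2 fold change was -1.04 (SE 0.36, edgeR adjusted p = 0.229), so part of the difference went with that index. Adrb1 had a log2 fold change of 0.19 (SE 0.40), and Adra2b lay below the filter with at most 4 counts in a library. Adrb3 had 1.69 ± 0.29 against 0.79 ± 0.40 CPM (edgeR adjusted p = 0.343). The adrenergic list was not called (camera adjusted p = 0.457).

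Of the inflammatory and barrier genes in the fixed panel, none passed in edgeR when adjusted over all genes. Tnf had 4.74 ± 2.60 CPM with PAGly and 7.68 ± 3.16 with saline, Il1b had 5.36 ± 2.56 and 7.31 ± 4.43, and the mucin gene Muc2 2979 ± 747 and 3083 ± 1219 (SD, n = 4). The tight junction genes Tjp1 and Ocln had 113 ± 35.3 and 54.3 ± 5.90 against 114 ± 20.1 and 66.4 ± 6.87 CPM. Their edgeR adjusted p ran from 0.389 for Ocln to 0.986 for Tjp1. Cldn1 stood at 1.27 ± 1.10 and 1.06 ± 0.73 CPM. Il6 and Il10 lay below the filter, with at most 18 and 5 counts in a library. The list of tight junction and adhesion genes had 16 of 22 members negative but was not called by camera (adjusted p = 0.0506). Its mean log2 CPM was 6.98 ± 0.054 against 7.12 ± 0.055. The groups did not overlap but nearly touched, with 7.04 in PAGly replicate 1 and 7.05 in saline replicate 2. Cldn4 was the list's 1 member that passed when adjusted over the list alone, with 11.1 to 33.5 CPM against 43.2 to 103.0.

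The libraries also differed in Hox genes, whose expression marks position along the gut. Hoxb13, a gene of the hindgut's posterior end, had 820, 878, 422 and 471 CPM in PAGly replicates 1 to 4 and 336, 1.72, 467 and 238 in saline replicates 1 to 4. Hoxb6, of the anterior genes, had 2.31, 2.88, 6.12 and 23.1 CPM with PAGly and 2.59, 102, 86.3 and 38.3 with saline. A Hox index, the mean log2 CPM of 5 posterior minus that of 9 anterior HoxB and HoxD genes, was chosen after the data were seen. It was 2.65 ± 1.82 with PAGly and -0.45 ± 4.23 with saline (SD, n = 4, exact permutation p = 0.286), with 4.89 in saline replicate 1 and -5.42 in saline replicate 2. Across the 8 libraries it followed the first principal component, which held 37.3% of the variance (Pearson r = -0.984, Spearman rho = -1). No test is given for this agreement, since the index was chosen from the same values. Without saline replicates 1 and 2, the libraries farthest from the median, r was -0.957.

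**Figure D4:**
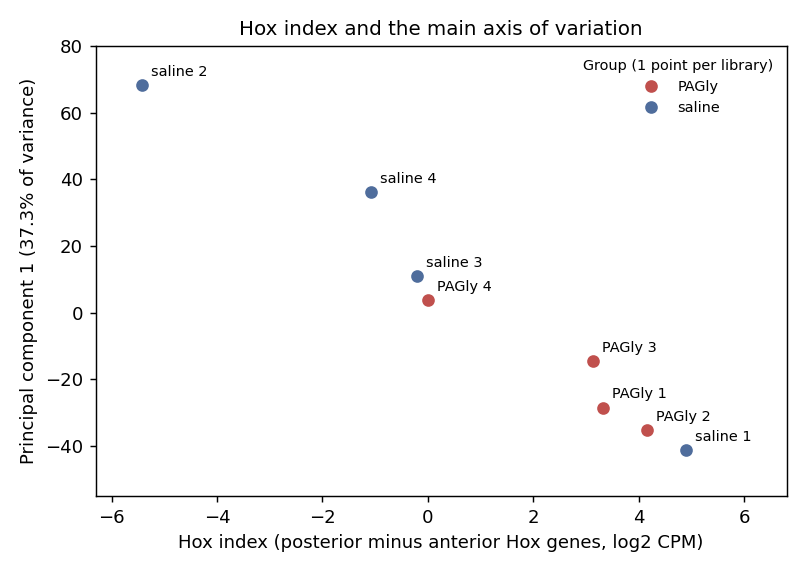
First principal component of log2 CPM (vertical axis, no unit) against the Hox index (horizontal axis, log2 CPM), with 1 labelled point per library, PAGly in red and saline in blue. Saline replicate 1 and PAGly replicates 1 to 3 lie at the posterior end, with indices of 3.12 to 4.89, and saline replicate 2 lies alone at -5.42.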

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

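The tests against the Hox index and of squamous and muscle genes were chosen only after the results were seen. Of 266 checks of whether 1 library lay far from the other 3 of its group, 10 did so, where chance gives about 1 in 20. Sema7a was 16.4 CPM in saline replicate 1 and 9.84 to 10.7 in the other saline libraries. Tnf was 3.04 CPM in saline replicate 2 against 8.31 to 9.70, Hoxb13 was 1.72 CPM there against 238 to 467, and Bst2 was 77.1 CPM in saline replicate 4 against 22.5 to 26.1. With PAGly, Muc2 was 4090 CPM in replicate 4 against 2520 to 2720, and Pfkl was 181 CPM in replicate 3 against 213 to 220. The mean log2 CPM of the fibroblast and matrix list was 5.17 in saline replicate 1 against 4.35 to 4.46, and that of endoplasmic reticulum stress genes was 6.28 there against 5.84 to 5.90. Enteric neuron and glia genes stood at 3.85 in PAGly replicate 3 against 3.06 to 3.16, and lipid and sterol synthesis genes at 6.90 in PAGly replicate 1 against 7.08 to 7.09.

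The first pattern was the absence of genes past edgeR's threshold beside 374 past that of DESeq2. Chance could not be excluded for the other counts: of the 35 splits of the 8 libraries, 5 gave at least the real split's 1772 genes at an unadjusted p under 0.05 in edgeR (highest other 2463), 2 gave at least its 374 genes in DESeq2 (highest other 738), and 12 gave at least its 15 lists (highest other 21). For edgeR's 0 genes past the threshold the splits decide nothing, since all 35 reach a count of 0 (highest other 17), and the highest gene counts came from the split that set saline replicate 1 with PAGly replicates 1 to 3, which follows the Hox index and points to a structure of the samples other than treatment. A spread of each group's libraries along the gut and a weak biological effect of PAGly cannot be told apart as reasons for the few calls. A share of 0.01 of random orders of the index lowered the residual variance as much as the real order, but this decides nothing, since the index was chosen after the data were seen and orders the libraries as the first principal component of the same values does.

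The second pattern was the set of lists that moved with PAGly, for which the groups' different mean Hox index may be a technical source. For fatty acid oxidation and ketogenesis, the difference in mean log2 CPM went from -0.52 (SE 0.31) to -0.119 (SE 0.119) with the index in the model. A difference in the position sampled would give this. An effect of treatment along the first principal component, which the index follows, would shrink in the same way. Position and treatment therefore cannot be told apart for this list. For hypoxia and glycolysis the difference in mean log2 CPM went from -0.41 to -0.578 (SE 0.0888), so the index did not take up this difference. Saline replicate 1, which had the highest index, also had the highest mean level of this list, at 7.93 log2 CPM. The larger fall may therefore rest on that library, and the index, chosen after the data were seen, does not decide the cause. Nor can position and treatment be told apart for the small intestine list, which went from -1.15 to -0.566 (SE 0.196). The same holds for the monocyte and macrophage list, which went from 0.64 to 0.398 (SE 0.191). Both remained within 1 SE of 50% of their size.

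The third pattern was squamous epithelium genes in PAGly replicate 1. A candidate source is tissue of the anal canal, whose lining is squamous and whose sphincter is skeletal muscle: the 4 tested skeletal muscle genes had a median log2 ratio of 1.88 to the highest other library, with Acta1 at 73.3 CPM in PAGly replicate 1 against 2.99 to 18.7 elsewhere and Mylpf at 26.5 against 0.52 to 1.19. The same would not account for Ckm, at 62.6 CPM there and 44.0 in saline replicate 2, unless muscle entered that library too. An effect of PAGly was not excluded, as 3 of the 4 PAGly libraries had a squamous level above every saline library (exact permutation p = 0.0571, n = 4). Saline replicate 1 came next at 2.05 log2 CPM. Those 3, PAGly replicates 1 to 3, and saline replicate 1 also had the highest Hox indices. Position and treatment therefore cannot be told apart for this list.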

How the results depend on the processing

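The number of genes called depended on the test more than on scaling or filtering, and the cause was not tested. The Hox index, the joint removal of PAGly replicate 1 and saline replicate 1, and the DESeq2 refits were chosen after the data were seen. edgeR's 0 genes higher and 0 lower became 188 and 186 in DESeq2, 26 and 50 with 1 surrogate variable, and 1 and 6 with limma-voom and quality weights. They became 1 and 8 with the Hox index, 0 and 4 with limma on log2(TPM + 1), 0 and 3 at an adjusted p under 0.1, and 0 and 1 without PAGly replicate 1 and saline replicate 1. They stayed at 0 and 0 with RLE factors, library totals, both other filters, the 20 most abundant genes removed, log2(TPM + 0.1), no robust option and the added fold threshold. With 1 library left out they ranged from 0 to 1 higher and from 0 to 4 lower, and DESeq2's from 36 to 438 higher and from 39 to 681 lower. DESeq2 with the Hox index called 285 and 290 genes, and 207 of its 374 calls without the index were called in the same direction with it. The 15 lists became 0 with an estimated correlation and 0 with fry, and ranged from 11 to 17 with 1 library left out and from 15 to 19 under the other settings with the preset correlation. All 15 called lists kept their direction in each of 270 recomputed values. Of these lists 9 stayed past the threshold whichever library was left out. The mast cell and eosinophil list was not called with no filter (adjusted p = 0.104) or the 1 CPM filter (0.111). Without PAGly replicate 1 and saline replicate 1 together, it (0.0737), interferon-stimulated genes (0.151) and endothelium (0.0621) were not called, and the Hox index ended 6 calls. The platelet list was past the threshold in no setting: its adjusted p ranged from 0.329 to 0.632 with 1 library left out, and its camera direction reversed with the Hox index (0.838).

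Of 88 genes recomputed, 78 kept their direction in every setting. No call was lost, since edgeR made 0, and 79 values passed the threshold in another setting, 42 of them in DESeq2. The other 10 were 9 panel genes and Siglecf, and 1 of them, Il1b, was past the threshold in DESeq2 with the Hox index (adjusted p = 0.0458). With the Hox index, log2 fold changes were 0.058 for Itgb3, 0.13 for Gp1ba, -0.13 for Thbs1, 0.40 for Muc2, -0.28 for Cldn1 and 0.34 for Siglecf. With the 2 libraries removed they were 0.25 for F3, -0.012 for Adrb1, 0.082 for Il1b, 0.12 for Tjp1 and -0.087 for Cldn1. With limma-voom they were 0.014 for Itgb3 and 0.33 for F3. With 1 surrogate variable they were 0.011 for F3 and 0.086 for Muc2, and F3 was 0.016 on log2(TPM + 1) and 0.020 on log2(TPM + 0.1). With 1 library left out they ranged from -0.15 to 0.087 for Itgb3, -0.35 to 0.068 for Gp1ba, -0.11 to 0.45 for Thbs1 and -0.32 to 0.54 for F3. They ranged from -0.25 to 0.16 for Muc2, -0.25 to 0.11 for Tjp1, -0.54 to 0.72 for Cldn1 and -1.25 to 0.076 for Siglecf. At these totals, 7 of the 25 panel genes lay below the count filter and were not tested in the main fit.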

Other observations

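Genes of the antimicrobial list went both ways. Wfdc2, a secreted protease inhibitor of epithelium, had 537 ± 293 CPM with PAGly and 160 ± 78.6 with saline, and the acute-phase gene Saa3 had 16.6 ± 7.47 against 47.6 ± 18.2 (SD, n = 4). Both passed in edgeR when adjusted over the list alone (adjusted p = 0.0402 each), with adjusted p = 0.236 each over all genes. In the goblet cell list Galnt12 had 62.0 ± 7.94 against 88.7 ± 8.31 CPM and passed over the list alone (adjusted p = 0.0482), while Agr2, which folds mucins, had 930 ± 171 against 538 ± 161. Ptgis, the prostacyclin synthase gene, had 9.98 ± 4.41 against 3.73 ± 0.26 CPM and was the 1 eicosanoid gene that passed over the list alone (adjusted p = 0.0235, and 0.215 over all genes in edgeR). Mfap4, a matrix protein gene of smooth muscle and fibroblasts, had 38.0 ± 5.82 against 9.14 ± 4.35 CPM, and the thioredoxin reductase gene Txnrd1 had 175 ± 10.6 against 249 ± 34.4. Mptx1, a pentraxin gene, ranged from 359 to 2168 CPM with PAGly and from 0.13 to 19.5 with saline, with an edgeR adjusted p of 0.196 and a DESeq2 adjusted p of 0.000146.

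The list of host genes of phenylalanine breakdown and glycine conjugation, not all of which serve to make PAGly, was not called (camera adjusted p = 0.834). In it Hpd had 49.8 ± 16.6 against 25.4 ± 9.03 CPM and Aldh1a1 27.6 ± 14.7 against 138 ± 125, of which saline replicate 2 alone had 314. Among clock genes, Per2 had 63.9 ± 6.73 against 40.3 ± 10.4 CPM and Cry1 14.4 ± 1.25 against 22.0 ± 4.45, and the list was not called (camera adjusted p = 0.457). The colonocyte carbonic anhydrase gene Car1 ranged from 648 to 4000 CPM with PAGly and from 2643 to 8102 with saline. With the Hox index as a covariate, a test chosen after the data were seen, edgeR called 9 genes, among them Slc16a3 (log2 fold change -1.93), Plaur (-1.71) and Mfap4 (2.64). Without the index these were -1.59, -1.33 and 2.06. Plaur stood at 44.3 CPM in saline replicate 1 against 10.5 to 16.5 in the other saline libraries. Its log2 fold change without the index ranged from -1.56 to -0.70 with 1 library left out. With the index camera called 17 lists, while 6 of the 15 called without it were no longer called. Of the 8 lists called only with it, 4 were lower with PAGly: proliferation with a median log2 fold change of -0.87 (camera adjusted p = 2.48e-11), inflammatory cytokines and chemokines with -1.12 (0.00552), neutrophils with -0.95 (0.0103) and regenerating epithelium with -0.80 (0.0106). The other 4 were higher: smooth muscle with 0.92 (1.41e-08), clock genes with 0.48 (0.0103), interferon-gamma and antigen presentation with 0.41 (0.0103) and goblet cells and mucus with 0.48 (0.0408). Saline replicate 1, which had the highest index, also had the highest mean level of each of the 4 lower lists. For proliferation it had 6.17 log2 CPM against 3.38 to 4.81 in the other libraries, so these falls may rest on that library. It also had the lowest mean level of smooth muscle (5.92 log2 CPM), clock (4.06) and goblet cell genes (7.28), so their rises may rest on it too. Without the index, the camera adjusted p was 0.917 for proliferation, 0.840 for cytokines, 0.969 for neutrophils and 0.813 for regenerating epithelium. In the same setting it was 0.0898 for smooth muscle, 0.457 for clock genes, 0.0506 for interferon-gamma and antigen presentation and 0.4825 for goblet cells and mucus. No list was called with both the index and an estimated correlation, the lowest adjusted p being 0.340.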
